A study of Rattus norvegicus with 20 samples.

How the data were processed

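Poly-A RNA sequencing of 20 libraries was used, 1 from the kidney cortex and 1 from the left ventricle of each of 10 rats. Groups follow the labels: 5 vehicle and 5 Maresin 1 (MaR1) animals per organ, with the animal number as replicate. The deposited table gives FPKM (fragments scaled by gene length and library size) for 30560 genes, made by the authors. Per the submitters' processing notes, reads were trimmed with fastp (version not given), aligned with HISAT2 2.0.5, assembled with StringTie 1.3.3b and counted with featureCounts 1.5.0-p3. The genome build is not given in the sources used here, so coordinates are as the file gives them, with Ensembl rat gene identifiers. Whether the libraries were stranded is not stated, so overlapping genes on opposite strands cannot be told apart.

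FPKM times gene length gave whole fragments, within 0.01 of a fragment, for 100% of 371175 values above 0. The library sizes the authors divided by equal a median-of-ratios scaling over all 20 libraries, computed on 14900 genes above 0 in every library, within 6.66e-14%. Assigned fragments ranged from 19383232 to 30342034 per library, and 12074 to 12670 genes reached 1 FPKM. The smallest chi-square per degree of freedom over all 190 pairs of libraries was 10.1 (10.2 within a group), so no library is a copy of another, and the spread between animals is well above counting error. The p-values describe the spread between animals.

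Values were analysed as log2(FPKM + 0.5), which understates fold changes of genes at low level. Genes with a mean FPKM of at least 1 over the libraries fitted were tested with limma 3.58.1 in R 4.3.3 (moderated variance with a trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. Each organ was fitted alone. A model of all 20 libraries tested the interaction, the response in heart minus the response in kidney, without an animal block. Single values were compared with exact permutation tests (two-sided; smallest p 0.00794 for 5 against 5). The correlation of the responses was compared with all 252 ways to choose 5 of the 10 animals, and correlations of scores used 100000 random permutations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

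Comparisons, tests, 55 gene lists (1273 of 1325 symbols matched, 96.1%) and the alternatives were fixed before the data were examined. Camera tested lists with at least 5 tested members at an inter-gene correlation of 0.01, again with an estimated correlation, and fry tested whether the genes of a list moved one way. The rule for named genes took, per organ, the genes past the threshold with all 5 MaR1 libraries on one side of the vehicle mean, filled up to 20 with the genes of smallest p. It added the genes of smallest p from each list that was called or that concerns lipids, mediators, inflammation, matrix or the organ, and a few genes tied to Maresin 1, injury or load. Unnamed and predicted loci were not named, and some genes that the rule names are not reported here, though tests and lists include them. Other genes (Adipoq, Upk1a, Myl7, Fst, and genes that passed only under an alternative) were chosen after their values were seen, as were the lists of urothelium, clock arms and other nephron segments and the alternatives without selected libraries or without genes 10 times higher in kidney. For 2 list symbols the only match was another gene, and they were dropped.

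Whether kidney and heart of an animal vary together was checked on 10987 genes after removing group means. Same-animal correlations ran from -0.00947 to 0.179, 3 were above 0.1, and 2 of 10 kidneys correlated best with their own heart, so no block entered the main models; limma with statmod 1.5.0 estimated a correlation of 0.0621 for the fit with the animal as block, which also joins both organs in 1 model; the joint model without the block was added after seeing the data. The steps were tested on simulated data with known changes. At 2-fold, 94.0% of changed genes were recovered in kidney, 88.1% in heart and 83.6% for the difference between organs. At 1.5-fold the shares were 68.7%, 50.7% and 55.2%. Each of these folds was put into 67 genes, along with others at 3-fold, all drawn from genes of higher level than the filter asks. Many true changes make the adjustment more lenient, so these shares do not tell how many changed genes a real count of 0 would miss. With no change put in, 0 genes and 0 lists were called; the simulated genes vary independently, which real genes do not.

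The alternatives were pseudocounts of 0.1 and 1, no filter and a mean FPKM of at least 5, median-of-ratios and quantile scaling, library weights, no variance trend, a robust prior, limma voom on the recovered fragments, the animal as block, and leaving out each animal in turn. All fixed alternatives were run. No gene was manipulated, so the treatment labels could not be checked.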

Results

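Messenger RNA was sequenced from the kidney cortex and the left ventricle of 10 male hypertensive rats that ate a diet with 4% NaCl for 3 weeks. The labels do not name the strain. Subcutaneous minipumps gave 5 rats vehicle and 5 rats Maresin 1 (MaR1), a lipid mediator that immune cells make from docosahexaenoic acid, at up to 1.3 µg/kg/day. Each rat gave 1 library per organ, so the 20 libraries form 4 groups of 5, and replicates are separate animals. The libraries held 19383232 to 30342034 fragments assigned to genes. In the kidney, the mean was 24.8 ± 3.83 M (mega) fragments with vehicle and 24.4 ± 2.11 M with MaR1 (SD, n = 5; exact permutation p = 0.825). In the heart it was 26.5 ± 2.61 M with vehicle and 23.6 ± 1.36 M with MaR1 (exact permutation p = 0.0476, adjusted p = 0.476 over 10 library measures). For a gene of 1 kb, 1 FPKM stood for 19.7 to 34.9 fragments, so counting error is small beside the spread between animals except for genes of low level. The organ labels matched the contents: 15 proximal tubule markers summed to 7190 to 12851 FPKM in kidney libraries and 14.7 to 55.2 FPKM in heart libraries. Means below are given ± SD with n = 5 animals, log2 fold changes ± SE are on the scale of log2(FPKM + 0.5), MaR1 over vehicle, and adjusted p-values come from limma or its set test camera.

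The kidney comparison asked which cortical transcripts differ between MaR1 and vehicle rats on high salt. The genes with the strongest evidence were mostly higher with MaR1, though no gene passed the test. Cldn23, which encodes a tight junction protein, averaged 0.919 ± 0.301 FPKM with vehicle and 3.08 ± 0.842 FPKM with MaR1, a log2 fold change of 1.33 ± 0.19 (adjusted p = 0.298). Igf1, the gene of insulin-like growth factor, averaged 2.79 ± 0.394 and 6.33 ± 1.90 FPKM (1.02 ± 0.17, adjusted p = 0.298). The urea transporter gene Slc14a1 averaged 0.242 ± 0.144 and 2.06 ± 1.02 FPKM, and Wnt7b, which encodes a secreted signal of the collecting duct, averaged 0.397 ± 0.276 and 2.27 ± 1.12 FPKM. On the lower side, Col4a3, a collagen chain of the glomerular basement membrane, averaged 21.3 ± 1.40 and 16.6 ± 1.51 FPKM (-0.36 ± 0.07, adjusted p = 0.444). Tpcn1, an ion channel gene of endosomes and lysosomes, averaged 49.6 ± 2.37 and 38.9 ± 3.67 FPKM (-0.35 ± 0.07). In each of these genes all 5 MaR1 kidneys lay on the same side of the vehicle mean. The genes were picked for small p, so that adds no support. Others among the 20 genes of smallest p were Tmem184a, Qsox1, Tspan12, Ly6al, Apcdd1, Plet1, Crip2, Rab25, Tspan8, Lamb3 and Hid1, with log2 fold changes of 0.43 to 1.19, and Npas2 and Cotl1, at -1.002 and -0.39. Markers of kidney regions also differed between the groups, as described below. Whether the genes named here followed those markers from kidney to kidney was not tested, so a difference in the tissue taken stays open for them. As the file gives positions, Cldn23 (ENSRNOG00000011424) spans 56413381 to 56415523 on chromosome 16 and Igf1 (ENSRNOG00000004517) spans 22282930 to 22359296 on chromosome 7.

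In the kidney, limma called 0 of 12446 genes at an adjusted p of 0.05, with 840 at an unadjusted p under 0.05 (408 higher, 432 lower) where chance gives 622. Leaving out 1 animal moved the 840 to between 486 (without RB038) and 1757 (without RB039). limma voom on recovered fragments also called 0, with 842 at an unadjusted p under 0.05. The groups did not overlap in 153 genes (1.23%), against 0.794% by chance. When both organs entered 1 model with the animal as a replicate block, which takes its spread from the heart libraries too, 6 kidney genes passed (7 without the block, the 6 among them), all higher with MaR1, among them Cldn23 (adjusted p = 0.00114), Tmem184a and Ly6al (adjusted p = 0.0162 each), Tspan12 (adjusted p = 0.0381) and Tspan8 (adjusted p = 0.0403). Whether these 6 genes followed the markers of kidney regions described below was not tested either. Among the kidney libraries alone, leaving out animal RB035 gave 1 gene in place of 0.

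**Figure D1:**
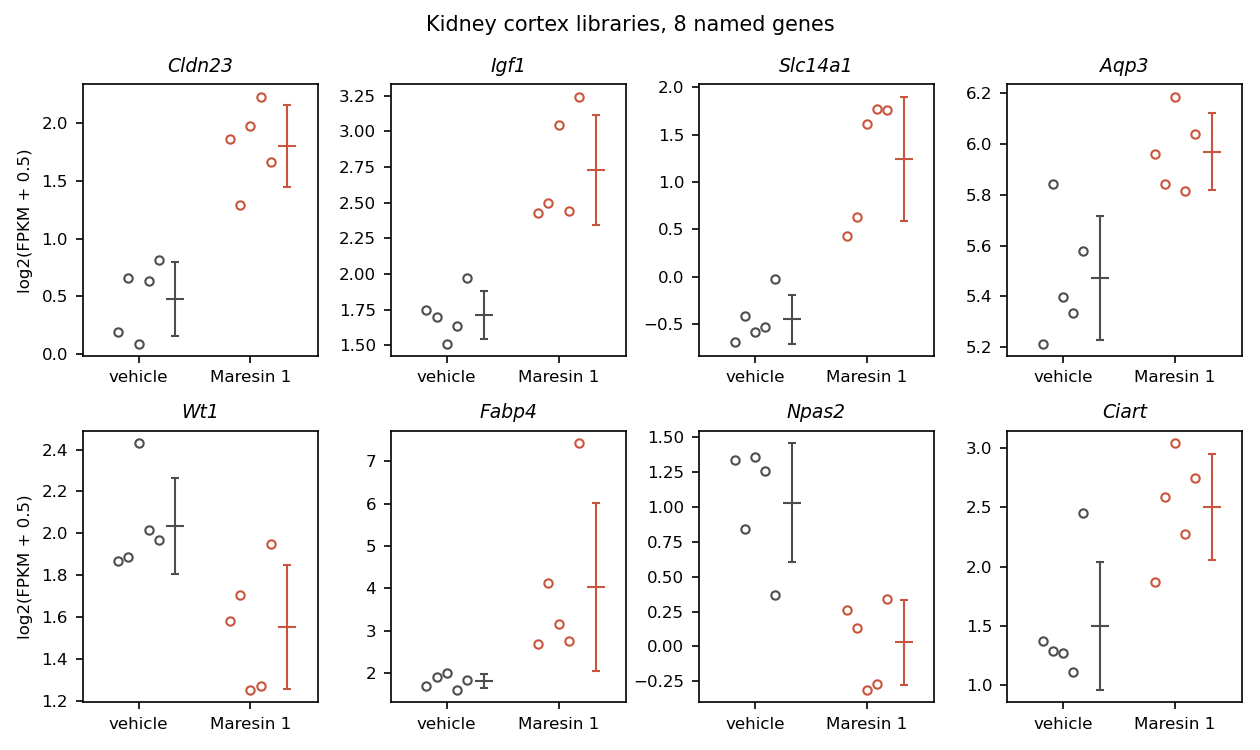
Expression of 8 named genes in the kidney cortex, as log2(FPKM + 0.5) on the vertical axis (its range differs between panels), for vehicle and Maresin 1 rats. Each circle is 1 animal, and the bar beside each group is the mean with its SD (n = 5); in Cldn23 the MaR1 kidneys lie at 1.95 to 4.20 FPKM and the vehicle kidneys at 0.564 to 1.26 FPKM, and in Fabp4 animal RB039 stands apart at 171.7 FPKM.

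Gene lists fixed before the data were examined showed markers of different kidney regions moving apart. Of 11 tested markers of the inner medulla and thin limb, 10 were higher with MaR1, with a median log2 fold change of 0.82, and 6 passed when adjusted over the list alone (0 over all genes). Camera called this list higher (adjusted p = 5.8e-07; adjusted p = 0.0847 with an estimated correlation), and it was the only kidney list that fry called (adjusted p = 0.0301). Its members include Slc4a11, a membrane transporter (0.842 ± 0.0925 and 2.54 ± 1.41 FPKM), and Fst, the activin-binding protein follistatin (1.36 ± 0.605 and 8.56 ± 6.05 FPKM). Podocyte markers went the other way, lower in 9 of 10, with a median of -0.25 and 4 past the threshold when adjusted over the list alone. Camera called them lower (adjusted p = 4.2e-05; adjusted p = 0.900 with an estimated correlation). The podocyte transcription factor Wt1 averaged 3.64 ± 0.717 and 2.48 ± 0.618 FPKM. All 15 proximal tubule markers were lower (median -0.27, 0 past the threshold over the list alone), among them the glucose transporter Slc5a2 (149 ± 13.9 and 111 ± 52.5 FPKM) and the dicarboxylate transporter Slc13a3 (396 ± 31.9 and 312 ± 110 FPKM). Camera called this list lower (adjusted p = 0.0015; adjusted p = 0.900 with an estimated correlation; adjusted p = 0.0565 without animal RB037). In the same libraries, markers of the urothelium, which lines the renal pelvis, were high in some kidneys: Upk1a stood at 4.33, 10.99 and 23.8 FPKM in MaR1 animals RB036, RB038 and RB039 and at 1.47 FPKM in vehicle animal RB034, against 0.123 to 0.434 FPKM in the other kidneys.

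Ion transport genes of the kidney went both ways, with 17 of 38 higher and 21 lower (median -0.03). An unadjusted p under 0.05 was seen for 8, each higher with MaR1, and 3 passed when adjusted over the list alone. Stk39, a kinase that activates sodium-chloride cotransporters, averaged 6.95 ± 0.630 and 9.05 ± 0.881 FPKM (adjusted p = 0.444 over all genes). Aqp3, a water channel of the collecting duct, averaged 44.4 ± 7.93 and 62.4 ± 6.70 FPKM. Camera did not call this list (adjusted p = 0.496). Whether its higher genes followed the inner medulla markers from kidney to kidney was not tested. Collecting duct markers were higher in 6 of 11, with 2 past the threshold over the list alone, and were not called (adjusted p = 0.251). Markers of the thick ascending limb and distal convoluted tubule were higher in 6 of 10 and were not called (adjusted p = 0.301).

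Adipocyte markers were higher in 13 of 13 genes, with a median log2 fold change of 1.38, and 0 passed over the list alone. Camera called them higher (adjusted p = 1.1e-06; adjusted p = 0.900 with an estimated correlation). Single animals carried much of this: the adipokine gene Adipoq stood at 120 FPKM in kidney RB039 and 13.2 FPKM in RB036, against 4.26 to 4.78 FPKM in the other MaR1 kidneys and 2.77 to 3.79 FPKM with vehicle. Without RB039 the mean log2 fold change of the list was 0.68 in place of 1.37 (adjusted p = 0.001055). Clock genes were higher in 14 of 19, and adjusted over the list alone 5 were higher and 2 lower. The repressor gene Ciart averaged 2.52 ± 1.38 and 5.39 ± 1.75 FPKM (log2 fold change 1.00 ± 0.27), while Npas2, an activator of the clock, averaged 1.61 ± 0.553 and 0.538 ± 0.211 FPKM. Camera called the clock list higher (adjusted p = 0.011; adjusted p = 0.900 with an estimated correlation; adjusted p = 0.137 without RB039). Cytosolic ribosomal protein genes were higher in 73 of 82 by a median of 0.07, with 0 past the threshold over the list alone, and were called (adjusted p = 6.2e-06; adjusted p = 0.900 with an estimated correlation). Leaving out 1 animal put the mean log2 fold change of these genes at 0.034 (without RB030) to 0.126 (without RB031), in place of 0.064. Their members of smallest p, Rps4x and Rpl36a, sit in the file at loci of 1 kb or less on chromosomes 4 and 10, and their reads may be shared with near-identical copies.

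Immune genes of the kidney split by group. Antigen presentation genes were lower in 16 of 17 (median -0.18), among them RT1-DMb, at 44.6 ± 5.55 and 36.6 ± 3.10 FPKM. Camera called the list lower (adjusted p = 0.00010; adjusted p = 0.900 with an estimated correlation), but not without animal RB030 (adjusted p = 0.0796). Interferon response genes were lower in 19 of 26, with Rsad2 at 3.02 ± 0.705 and 2.06 ± 0.348 FPKM, and were called (adjusted p = 0.0075; adjusted p = 0.900 with an estimated correlation). That call ended without RB030, RB036 or RB039 (adjusted p = 0.406, 0.0812 and 0.274). Cytokine, chemokine and adhesion genes were lower in 18 of 24 and were called (adjusted p = 0.0485; adjusted p = 0.900 with an estimated correlation). This last call ended without RB030, RB032, RB033, RB036 or RB039 (adjusted p = 0.947, 0.101, 0.162, 0.0761 and 0.4996). Examples are Nfkb2, at 10.7 ± 1.75 and 8.95 ± 0.638 FPKM, and Ccl20, at 1.53 ± 0.599 and 0.923 ± 0.418 FPKM. Macrophage markers were higher in 16 of 18 (median 0.18), with Folr2 at 2.54 ± 0.989 and 3.76 ± 1.04 FPKM, and were called (adjusted p = 0.016; adjusted p = 0.900 with an estimated correlation). Leaving out RB031, RB034 or RB037 ended that call (adjusted p = 0.405, 0.598 and 0.301). In these 4 lists 0 members passed when adjusted over the list alone. In all, camera called 10 of 46 kidney lists with its preset correlation and 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05. Fry called 1, with 2 at an unadjusted p under 0.05, and other splits of the 10 animals called a median of 16 lists. For the means of the called lists, the unadjusted exact permutation p was 0.00794 for inner medulla and for adipocytes. It was 0.0556 for podocytes, 0.111 for clock genes, 0.151 for antigen presentation and 0.254 for proximal tubule. For interferon, macrophage, ribosomal and cytokine lists it was 0.310, 0.365, 0.429 and 0.5.

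The title of the study names lipids, so the lipid lists were examined in full in the kidney. None of 8 lists of lipid metabolism and lipid mediator genes was called, nor was the list of mediator receptors: their medians lay between -0.02 and 0.05, with camera adjusted p-values of 0.405 to 0.764. Single genes stood out without passing the test. Cpt1b, whose enzyme readies long-chain fatty acids for entry into mitochondria, averaged 2.05 ± 0.3299 and 6.52 ± 4.61 FPKM, with 14.3 FPKM in RB039, where Adipoq was highest. Plin2, a coat protein of lipid droplets, averaged 27.8 ± 4.52 and 21.3 ± 2.98 FPKM (log2 fold change -0.38 ± 0.13, adjusted p = 0.661). Ptgs1, the constitutive cyclooxygenase, averaged 2.44 ± 0.692 and 4.02 ± 0.877 FPKM, the prostaglandin receptor Ptgfr averaged 1.69 ± 0.263 and 2.59 ± 0.543 FPKM, and the omega-hydroxylase Cyp4a1 averaged 30.9 ± 5.48 and 21.5 ± 8.57 FPKM. Whether single genes such as these followed the inner medulla markers from kidney to kidney was not tested. The remaining members of smallest p had log2 fold changes of 0.19 for Acadm, 0.26 for Acsl5, 0.23 for Pmvk, 0.28 for Idi1, 0.46 for Mboat2, 0.52 for Acacb, 0.55 for Ugt8, 0.35 for Ptger3 and -0.19 for Sptlc2. Acadm ran from 0.073 (without RB030) to 0.27 (without RB031) when 1 animal was left out. Cidec, Dgat2 and Fabp4 were at 1.25, 0.81 and 2.22, each with its highest value in RB039. Genes of the extracellular matrix were higher in 18 of 33 and were not called (adjusted p = 0.360), and tubular injury genes were lower in 17 of 22 (adjusted p = 0.0628). The injury markers Havcr1 (47.2 ± 34.8 and 32.4 ± 6.76 FPKM) and Lcn2 (16.7 ± 9.68 and 15.3 ± 5.84 FPKM) varied more between animals than between groups. Of the genes of Maresin 1 receptors, Rora differed by -0.04 (95% interval -0.29 to 0.22), and Lgr6 lay below the filter at 0.694 ± 0.156 and 0.883 ± 0.201 FPKM, as did Alox12 and Alox15, whose enzymes oxygenate polyunsaturated fatty acids. Il1b and Ccl2 differed by 0.15 and -0.19, within the spread between animals.

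The heart comparison asked the same of the left ventricle. The genes with the strongest evidence were again mostly higher with MaR1, and again none passed the test. Eya2, a transcriptional coactivator, averaged 3.44 ± 1.26 FPKM with vehicle and 7.26 ± 1.13 FPKM with MaR1, a log2 fold change of 1.03 ± 0.21 (adjusted p = 0.797). Myrip, a linker between secretory vesicles and actin motors, averaged 10.2 ± 1.27 and 15.3 ± 1.84 FPKM (0.56 ± 0.11, adjusted p = 0.797). Bmyc, a relative of the Myc gene, differed little but evenly, at 9.18 ± 0.215 and 10.8 ± 0.167 FPKM (0.23 ± 0.05, adjusted p = 0.797). Kap, a gene that proximal tubules express at high level under androgen control, averaged 2.80 ± 1.65 and 23.2 ± 17.1 FPKM (2.61 ± 0.58, adjusted p = 0.877). On the lower side, Impact, a translational regulator, averaged 8.28 ± 0.709 and 6.57 ± 0.505 FPKM, and Stxbp6, a regulator of vesicle fusion, averaged 9.96 ± 0.955 and 7.88 ± 0.640 FPKM. In each of these genes all 5 MaR1 hearts lay on the same side of the vehicle mean, which again adds no support for genes picked by p. Others among the 20 genes of smallest p were Irx1, Snord35b, Prkd1, Fnip2, Ppdpf, Slc7a13, Eef2k, Rps6kl1, Ocel1, Fmnl3, Pigl and Rab40c, with log2 fold changes of 0.24 to 1.40. Snord35b is a small RNA of 87 bases whose reads cannot be told from those of a gene it lies in. Eya2 (ENSRNOG00000019203) spans 154335400 to 154518793 on chromosome 3 and Kap (ENSRNOG00000005858) spans 166674595 to 166677639 on chromosome 4.

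In the heart, limma called 0 of 12237 genes at an adjusted p of 0.05, with 563 at an unadjusted p under 0.05 (376 higher, 187 lower) where chance gives 612. Leaving out 1 animal moved the 563 to between 394 (without RB037) and 956 (without RB035). limma voom called 0, with 550 at an unadjusted p under 0.05. The groups did not overlap in 103 genes (0.842%), against 0.794% by chance.

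**Figure D2:**
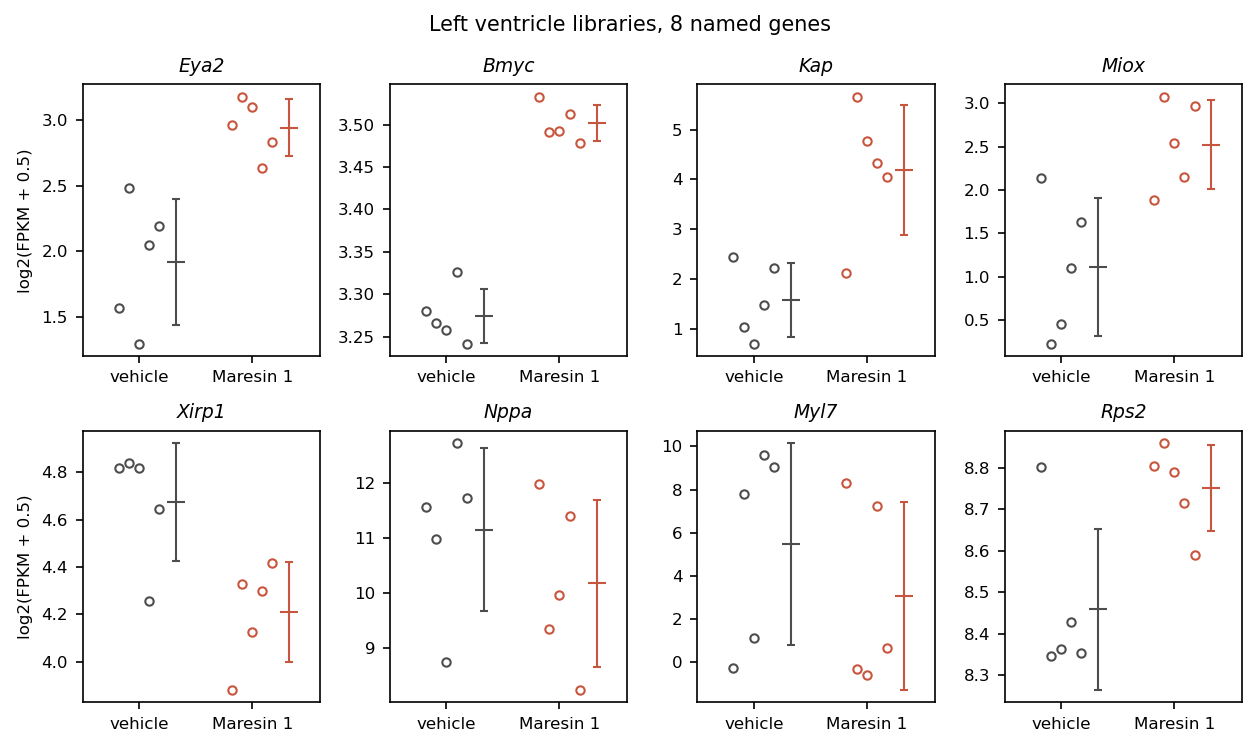
Expression of 8 named genes in the left ventricle, as log2(FPKM + 0.5) on the vertical axis (its range differs between panels), for vehicle and Maresin 1 rats. Each circle is 1 animal, and the bar beside each group is the mean with its SD (n = 5); Myl7, an atrial myosin light chain, splits the hearts into 5 at 151 to 784 FPKM and 5 at 0.163 to 1.65 FPKM, with both treatments on each side.

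Gene lists of the heart pointed to ribosomal, proximal tubule, hypertrophy and injury genes. Cytosolic ribosomal protein genes were higher in 70 of 82 (median 0.10, 0 past the threshold over the list alone), for example Rps2, at 354 ± 51.8 and 431 ± 30.4 FPKM, and Rpl17, at 175 ± 20.8 and 211 ± 19.8 FPKM. Camera called them higher (adjusted p = 2.0e-07; adjusted p = 0.9499 with an estimated correlation). The 5 proximal tubule markers above the filter were all higher in MaR1 hearts (median 0.83), and 2 passed when adjusted over the list alone, among them Miox, the inositol oxygenase of the kidney (1.94 ± 1.33 and 5.53 ± 2.06 FPKM). Camera called this list higher (adjusted p = 0.00027; adjusted p = 0.9499 with an estimated correlation). In the same hearts, the 39 transcripts with a mean of at least 200 FPKM over all kidneys and at most 1% of it over all hearts stood at 0.292 ± 0.127% of their kidney level with MaR1 and 0.113 ± 0.0740% with vehicle (exact permutation p = 0.0317). Genes of cardiac hypertrophy and the fetal programme were lower in 21 of 26 (median -0.13, 0 past the threshold over the list alone) and were called (adjusted p = 0.014; adjusted p = 0.287 with an estimated correlation; adjusted p = 0.0905 without animal RB030). Xirp1, an actin-binding protein of the intercalated disc, averaged 25.3 ± 4.04 and 18.2 ± 2.61 FPKM, and the transcription factor Gata4 averaged 34.2 ± 2.90 and 30.1 ± 2.81 FPKM. Several members of this list mark atrial tissue, whose transcripts differed between libraries: Myl7 stood at 225, 784 and 529 FPKM in vehicle hearts RB031, RB033 and RB034 and at 316 and 151 FPKM in MaR1 hearts RB035 and RB038. Without these 5 libraries, an alternative chosen after seeing the data, vehicle hearts RB030 and RB032 and MaR1 hearts RB036, RB037 and RB039 were left. Camera with its preset correlation then called 11 lists, with the hypertrophy list still among them (adjusted p = 0.00973) and the ribosomal list not (adjusted p = 0.780). So few hearts cannot show that the hypertrophy call is free of atrial tissue. The natriuretic peptide gene Nppa averaged 3106 ± 2308 and 1723 ± 1566 FPKM (log2 fold change -0.97, 95% interval -2.76 to 0.83), Nppb averaged 301 ± 106 and 247 ± 86.5 FPKM, and the slow myosin gene Myh7 averaged 640 ± 171 and 541 ± 169 FPKM. Leaving out 1 animal put their log2 fold changes at -1.56 (without RB032) to -0.48 (without RB039) for Nppa, -0.44 (without RB031) to -0.11 (without RB039) for Nppb and -0.39 (without RB035) to -0.06 (without RB039) for Myh7.

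Tubular injury genes were lower in 12 of 16 in the heart, with Clu, a secreted chaperone also made by heart cells, at 582 ± 71.0 and 488 ± 59.2 FPKM and 0 members past the threshold over the list alone. Camera called the list lower (adjusted p = 0.034; adjusted p = 0.9499 with an estimated correlation), a call that ended without RB030, RB033, RB034, RB036, RB037 or RB039 (adjusted p = 0.0930, 0.240, 0.0598, 0.235, 0.150 and 0.297). Extracellular matrix genes were lower in 29 of 36 (median -0.17) and were not called (adjusted p = 0.0592; adjusted p = 0.9499 with an estimated correlation; exact permutation p = 0.675 for the mean of the list), for example Mmp14 at 18.8 ± 4.79 and 14.3 ± 5.59 FPKM and Eln at 69.0 ± 22.6 and 54.9 ± 23.4 FPKM. The mean of the list was highest in hearts RB035 (MaR1), RB033 and RB034 (vehicle), at 1.09, 0.759 and 0.257 from the mean of all hearts, and these are 3 of the 5 hearts with abundant Myl7. Cytokine, chemokine and adhesion genes were lower in 14 of 24 (adjusted p = 0.368), with Vcam1 at 6.54 ± 1.10 and 4.95 ± 2.74 FPKM and Nfkb2 at 11.7 ± 0.730 and 10.7 ± 0.433 FPKM. Camera called 4 of 50 heart lists with its preset correlation, and 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05. Fry called 0, with 3 at an unadjusted p under 0.05, and other splits of the animals called a median of 16 lists. For the means of the 4 called lists, the unadjusted exact permutation p was 0.0317 for proximal tubule and 0.175 for ribosomal proteins. It was 0.214 for hypertrophy and 0.484 for injury.

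None of the 8 lipid lists, nor the list of mediator receptors, was called in the heart, with medians between -0.04 and 0.04 and camera adjusted p-values of 0.368 to 0.909. Plin2 averaged 30.8 ± 1.46 FPKM with vehicle and 26.5 ± 1.81 FPKM with MaR1 (log2 fold change -0.21 ± 0.07, adjusted p = 0.998), and was lower in all 5 MaR1 hearts than in each vehicle heart. Hmgcs1, an enzyme of cholesterol synthesis, averaged 8.52 ± 0.515 and 7.42 ± 0.192 FPKM. G0s2, an inhibitor of triglyceride lipase, averaged 19.1 ± 2.83 and 13.8 ± 4.61 FPKM, and the epoxide hydrolase Ephx1 averaged 10.96 ± 3.23 and 15.04 ± 2.50 FPKM. The other members of smallest p had log2 fold changes of 0.16 for Acaa1a, 0.18 for Cpt1a, -0.18 for Vnn1, 0.15 for Elovl1, 0.12 for Acsl5, 0.20 for Mvd, -0.13 for Pisd, 0.23 for Lpin3, 0.20 for Sgms1, -0.23 for Acer3, 0.41 for Alox5ap, 0.24 for Tbxa2r and 0.18 for Ptger1. Such values moved when 1 animal was left out, for example 0.062 (without RB035) to 0.24 (without RB033) for Elovl1. Acsl5 ran from 0.061 (without RB031) to 0.20 (without RB039). Lgr6, the gene of a membrane receptor of Maresin 1, was well expressed in the ventricle at 9.13 ± 0.973 and 9.67 ± 1.52 FPKM and differed by 0.07 (95% interval -0.18 to 0.32). Rora differed by -0.12, Alox15 by -0.28 and Ccl2 by -0.04, none past the test, while Il1b and Alox12 lay below the filter.

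**Figure D3:**
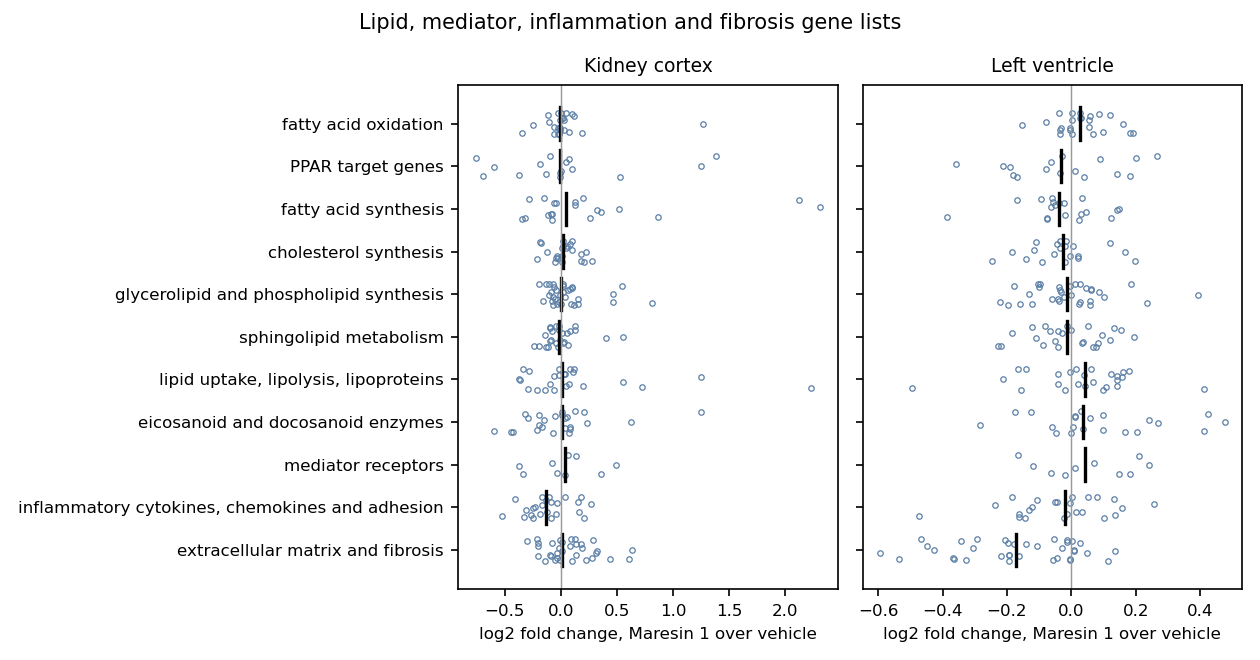
Log2 fold change, Maresin 1 over vehicle, of each tested member (circles) of 11 gene lists of lipid metabolism, lipid mediators, inflammation and fibrosis in kidney cortex and left ventricle, with the median of each list as a black bar. The horizontal axes differ in range between the organs; the medians of the lipid lists lie between -0.04 and 0.05 in both, and that of the matrix list in the heart at -0.17.

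A test of the difference between the organs asked whether any gene responded differently in heart and kidney. Cldn23 had the larger response in the kidney: the log2 fold change in heart minus that in kidney was -1.33 ± 0.23 for Cldn23 (1.33 in kidney and -0.01 in heart, adjusted p = 0.111). Spp2, which encodes a secreted phosphoprotein, went the other way, at -0.41 in kidney and 1.51 in heart, a difference of 1.92 ± 0.34 (adjusted p = 0.111). Ly6al and Abcg3l1 followed, with differences of -1.23 ± 0.27 and 0.69 ± 0.15 (adjusted p = 0.396 each). limma called 0 of 12984 genes, with 714 at an unadjusted p under 0.05 (464 without RB038 to 1233 without RB039), and voom called 0, with 586. Leaving out 1 animal gave 3 genes without RB035 (Cltrn and Spp2 among them), Cldn23 without RB036, and Spp2, Tspan8 and Smim5 without RB039; library weights gave 21 genes. Over the 10987 genes tested in both organs, the fold changes of kidney and heart were hardly related, with Pearson r = 0.06 across genes and Spearman rho = 0.06. Genes are not independent replicates, so the reference was the same value for the other splits of the 10 animals (exact permutation p = 0.690 for r and p = 0.690 for rho); without animal RB030 r was -0.02.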

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

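The tests of medulla content, of renal pelvis epithelium as a whole source, of time of day and of the RORA target genes, the comparisons over markers tested in both organs, the simulation and the pairing test of carry-over, and the choice of kidney-abundant genes over all libraries and their sorting by the proximal tubule score, were chosen only after the result was seen. Of 243 groups of named-gene and library values tested for a library far from the other 4 of its group, 13 had one, where chance gives about 1 in 20. The kidney of MaR1 animal RB039 stood apart in Cidec (45.01 FPKM, the others 16.9 to 22.7), Dgat2 (50.71, the others 10.9 to 17.0), Fabp4 (171.7, the others 5.93 to 17.0), Col14a1 (4.495, the others 0.817 to 1.65), Eln (20.49, the others 5.76 to 9.83) and Krt18 (16.49, the others 7.40 to 9.93). Among vehicle kidneys, RB030 stood apart in Ccl20 (2.585 FPKM, the others 1.16 to 1.37). RB034 stood apart in Ciart (4.972 FPKM, the others 1.66 to 2.10) and Il1b (0.4653, the others 1.06 to 1.23), and RB032 in Wt1 (4.887, the others 3.15 to 3.54). Among hearts, vehicle animal RB030 stood apart in Rps2 (445.7 FPKM, the others 325 to 344), and MaR1 animal RB036 in Slc7a13 (5.349, the others 1.71 to 2.39) and Pigl (1.107, the others 1.49 to 1.62).

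The mean response of the inner medulla and thin limb markers differed between the organs by -0.8434 (0.83 over 11 markers in kidney and -0.02 over 6 in heart; exact permutation p = 0.00794, adjusted p = 0.349 over 44 lists), and by -0.61 over the 6 tested in both (exact permutation p = 0.00794, adjusted p = 0.349). One candidate explanation is more medulla in the MaR1 kidney pieces: over the 10 kidneys the medulla score fell as the podocyte score rose, with Pearson r = -0.9313 (permutation p = 0.0001, adjusted p = 0.000195 over 3 relations), Spearman rho = -0.842 (permutation p = 0.00383), r = -0.818 without the 2 kidneys farthest from the median and r = -0.919 after group means were removed (permutation p = 6e-05). Proximal tubule markers followed less closely (Pearson r = -0.732, permutation p = 0.0156, adjusted p = 0.0156; rho = -0.455, permutation p = 0.190), and that relation rests on 2 kidneys, without which r was -0.180. Renal pelvis epithelium as the whole source is argued against in MaR1 kidneys RB035 and RB037. Their urothelium scores were no higher than the highest vehicle kidney (Upk1a at 0.252 and 0.434 FPKM), yet their medulla scores lay above the vehicle kidneys by 0.9663. The exact permutation p of 0.0476, the smallest possible for 2 against 5, adds nothing to this. Every MaR1 kidney scored above every vehicle kidney, so any 2 of them would give it. Kidney RB039, with Upk1a at 23.8 FPKM, had the lowest medulla score of the MaR1 kidneys (-0.119). A part from that epithelium stays open, since the score of 13 urothelium markers was higher with MaR1 by 1.243 ± 0.559 (SE, exact permutation p = 0.0556), as does an effect of MaR1 on these cells.

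The mean response of the proximal tubule markers differed between the organs by 1.168 (-0.26 over 15 markers in kidney and 0.91 over 5 in heart; exact permutation p = 0.0238, adjusted p = 0.524), and by 1.12 over the 5 tested in both (exact permutation p = 0.0317, adjusted p = 0.698). Induction of proximal tubule genes alone in heart cells was examined with 27 kidney-abundant genes outside the lists. Of these, 96.3% were higher in MaR1 hearts (exact permutation p = 0.0238 for their mean), above the bound of 75% set beforehand. But 16 of the 27 follow the proximal tubule score over the kidneys more closely than that of other segments, so this share cannot decide. All 11 that do not were higher too (median log2 ratio 0.90, exact permutation p = 0.0476 for their mean). They argue against such induction only as far as the sorting holds. That sorting rests on correlation over the kidneys and not on known cell types, and an effect of MaR1 on a wider set of kidney-abundant genes in the heart was not tested. Kidney RNA or reads from any kidney may still be present, since 11 genes of other nephron segments summed to 3.10 ± 1.502 FPKM with MaR1 and 2.35 ± 1.63 with vehicle, a log2 ratio of 0.4042 that leaves it open (exact permutation p = 0.333). Carry-over from the same animal's kidney stays open too: that kidney ranked first for 1 of 10 hearts (95% interval 0.253% to 44.5%; 1, 2 and 9 were its ranks in RB039, RB036 and RB037, with most kidney transcripts, and simulated carry-over with counting noise alone ranked it first for 7), which meets the bound of at most 2 set beforehand but not by more than its spread, and hearts correlated with their own kidney at a mean r of 0.127, against -0.0189 over all pairings within the groups (exact permutation p = 0.0623, one-sided).

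A clock score, built after the values of its genes were seen, was higher with MaR1 by 0.99 in kidney (exact permutation p = 0.0317) and 0.78 in heart (exact permutation p = 0.0476), while the mean of the 19 tested genes of the fixed clock list missed the threshold (exact permutation p = 0.111 in kidney and 0.0873 in heart; camera adjusted p = 0.011 and 0.0522, and 0.900 and 0.9499 with an estimated correlation). A different time of day at collection is a candidate explanation: the scores of the organs of an animal went together, with Pearson r = 0.9297 (permutation p = 0.00013, adjusted p = 0.000195 over 3 relations), Spearman rho = 0.782 (permutation p = 0.0104), r = 0.876 without the 2 animals farthest from the median and r = 0.870 after group means were removed (permutation p = 0.00081). Vehicle animal RB034, whose Ciart level stands apart, scored 0.594 and 0.340 and lay with the MaR1 animals. The RORA targets Arntl and Npas2 were lower and not higher, with a mean log2 fold change over both organs of -0.7851 (exact permutation p = 0.0238). That test was chosen after Npas2 was seen to be lower. Both are clock genes, which a shift of the clock would also move, so the test cannot decide whether RORA was activated. A shift of the clock by MaR1 in the whole animal predicts the same relation between organs and stays open.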

How the results depend on the processing

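The alternatives without chosen libraries (RB030 and RB039, or the 5 hearts with atrial transcripts) and without kidney-high genes, and both organs in 1 fit without a block, were chosen after seeing the data. Of 2669 values of named genes, 2632 kept direction and side of the threshold, 20 passed it and 17 reversed. No named gene passed in the main fits and most were picked for small p, so this share does not measure robustness. Of 323 list values, 258 kept both, 64 lost the call and 1 reversed. In the kidney, both organs in 1 fit called 6 genes with the animal as block and 7 without it (6 shared), in place of 0, so the move came with the joint fit and not with the block; the heart count stayed at 0 in both, and leaving out 1 animal gave 0 to 1 in kidney. Kidney lists called numbered 17 without RB030 and RB039 (7 of the 10 kept), 0 with an estimated correlation and 1 by fry, against 10; leaving out 1 animal gave 7 to 13. Heart lists called numbered 9 with no filter, 9 with library weights, 11 without the 5 hearts (3 of 4 kept), 2 without kidney-high genes, 0 with an estimated correlation and 0 by fry, against 4; leaving out 1 animal gave 3 (without RB030) to 13 (without RB035). Genes whose response differed between organs numbered 1 at pseudocount 0.1, 21 with library weights, 1 with no variance trend and 0 to 3 when 1 animal was left out. The correlation of the responses ran from -0.0207 (without RB030) to 0.141 (without RB031). Without RB030 and RB039, kidney Havcr1 was at 0.0378, Lcn2 at 0.448, Ccl2 at 0.0056 and the cytokine list at 0.0354; without the 5 hearts, Acsl5 was at -0.0336 and Ccl2 at 0.223. Leaving out 1 animal put kidney Rora at -0.10 to 0.043, Havcr1 at -0.52 to 0.048, Lcn2 at -0.20 to 0.23 and Il1b at -0.0036 to 0.28, and heart Alox15 at -0.60 to 0.041 and Ccl2 at -0.22 to 0.18. Over the alternatives, adjusted p-values ran from 0.00058 to 0.270 for the kidney clock list (lost with no filter, library weights and without RB039), 0.00043 to 0.947 for cytokines, 1.7e-08 to 0.955 for interferon, 3.5e-09 to 0.598 for macrophages, 3.1e-07 to 0.235 for antigen presentation and 1.0e-06 to 0.0565 for proximal tubule; in the heart, from 4.3e-05 to 0.297 for injury, 0.0010 to 0.0905 for hypertrophy and 1.1e-12 to 0.780 for ribosomal proteins. With an estimated correlation no list was called, and fry called inner medulla in kidney alone. The other settings kept the preset correlation. In them, the calls for ribosomal proteins, adipocytes, podocytes and inner medulla in kidney, and for proximal tubule in heart, held wherever 5 members remained. A mean FPKM of at least 5 left fewer for inner medulla in kidney and proximal tubule in heart. Leaving out kidney-high genes did so for the latter. Apart from the joint fit, the cause was not tested for any of these. Median-of-ratios scaling over both organs changes nothing in the interaction, since the authors' values already carry it. Genes such as Lgr6 in kidney and Il1b in heart were left out by the fixed filter, and no test set depth as the limit.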

Other observations

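The tests of other splits for counts at adjusted p 0.05 were chosen only after the result was seen. In the heart, markers of endothelium were higher with MaR1 in 12 of 14 and clock genes in 13 of 19. Neither list was called (camera adjusted p = 0.0522 each, and 0.9499 each with an estimated correlation). The means of the lists had an exact permutation p of 0.540 for endothelium and 0.0873 for clock genes. Markers of nerve and glia were lower in 10 of 11 (median -0.22, adjusted p = 0.368), and transcripts coded by the mitochondrial genome were lower in 11 of 13 (adjusted p = 0.383). Those transcripts took 28.2 ± 4.32% of fragments with vehicle and 27.1 ± 2.89% with MaR1 (SD, n = 5; exact permutation p = 0.635). In the kidney, immediate early genes were lower in 15 of 21 (adjusted p = 0.109), cell cycle genes were lower in 20 of 27 (adjusted p = 0.125) and genes of endoplasmic reticulum stress were higher in 15 of 21 (adjusted p = 0.2499).

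Some libraries held transcripts of tissue beside the one named. Kidney RB039 had the brown fat gene Ucp1 at 106 FPKM and the lipid droplet gene Plin1 at 45.0 FPKM, and RB036 had them at 5.93 and 5.80 FPKM. In the other kidneys they lay at 0 to 0.442 and 0.0341 to 0.128 FPKM. Among hearts, Adipoq was highest in RB034 (18.1 FPKM, vehicle) and RB035 (7.66 FPKM, MaR1).

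Other splits of the 10 animals (100 with the real one) were run for each count. At adjusted p 0.05 the real counts were 0, which every split reaches, so these tests say nothing: 100 of 100 splits in kidney (up to 18 genes in another split), 100 in heart (up to 185) and 100 for the difference between organs (up to 135). For the counts below, the splits did not allow chance to be excluded. At an unadjusted p under 0.05, the kidney had 840 genes against up to 3252 (24 splits gave as many), the heart 563 against up to 3460 (30 splits) and the difference between organs 714 against up to 2401 (29 splits). The medians of the other splits were lower, at 330 in kidney, 349 in heart and 430 for the difference between organs. Leaving out 1 animal moved these counts to 486 (without RB038) to 1757 (without RB039), 394 (without RB037) to 956 (without RB035) and 464 (without RB038) to 1233 (without RB039). Kidney lists called numbered 10 against up to 27 (84 splits), and heart lists 4 against up to 27 (96 splits), with a median of 16 in the other splits of each. Splits with several times the real count point to a structure of the samples other than treatment, and camera with its preset correlation calls many lists in such splits.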
